A study of Caenorhabditis elegans with 2 samples.

How the data were processed

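Chromatin immunoprecipitation with an anti-GFP antibody was followed by sequencing in 2 biological replicates of whole young adult hermaphrodites that express MADF-10 fused to GFP and FLAG, per the labels. Chromatin was sheared by sonication, per the labels. Both samples formed 1 group, taken from the strain and tag in the labels, and the replicate numbers are those of the labels. Per the deposited readme files, each replicate's region list was derived from that replicate's alignments and a control file, the pooled list from both replicates' alignments, and the reproducible list from the replicates' and pooled lists by an irreproducible discovery rate (IDR) threshold. The labels name a control experiment whose own data were not analysed here. The aligner, the peak caller, its settings and the IDR threshold are not given in the sources used here.

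The lists hold peaks and background regions in narrowPeak format for builds ce10 and ce11. The authors' signal value of each region (column 7 of the deposited lists) was used to rank regions and to describe them within a list. The deposited −log10 q column was not used, since it ends at a ceiling value in each list. On ce11 the reproducible list is exactly the 1869 strongest regions of the pooled list by signal, and on ce10 it is the 2878 strongest. Regions lie between 92.3 and 19717 in signal in the ce11 list. Depth per sample is not given in the sources used here. Most regions of a list have the same width (430 bp in replicate 1, 420 bp in replicate 2), so widths carry little information on weak regions. Signal tracks and alignments were not used here.

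Coordinates are those of ce11, counted from 1. The sequence and chromosome names of WBcel235, the assembly behind ce11, were used with Ensembl annotation release 115, which has 19985 protein-coding genes. The ce10 lists were only counted and compared among themselves, without conversion of coordinates. A promoter window ran from 1000 bp upstream to 200 bp downstream of an annotated protein-coding transcript start, and a peak counted for each gene whose window held its summit. Summits outside promoter windows were assigned to 5' UTR, coding sequence, 3' UTR, intron, non-coding gene or pseudogene, or intergenic, in that order. As no control library was among the samples, the background was taken from the same libraries: the 14838 regions in the lower 50% of the pooled list by signal that overlap no reproducible peak. These weak regions were themselves called by the authors and are not a random sample of the genome. For each replicate, the 1869 strongest regions of its own list were analysed in the same way, and the values of both replicates give the means and SDs. Since the pooled list contains both replicates, those lists are not independent of it.

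Shares were compared by Fisher's exact test, and the share of peaks on X and in chromosome centres by an exact binomial test. Medians and means were compared by permutation tests with 100000 resamples, so that the smallest p is 1e-05. All tests were 2-sided, except that the overlap of the replicates was set against 1000 random placements of the regions of replicate 1 on the same chromosomes, 1-sided, with a smallest p of 0.001. Adjusted values follow Benjamini and Hochberg within each family, with a threshold of 0.05. Intervals are exact binomial 95% intervals and cover counting error only. Regions and genes are not replicates, so p-values describe these lists. Sequences of 6 bases were counted once per window of 50 bp to either side of a summit, on both strands, against windows 300 bp to either side of the same summits. The 10 with the largest excess on chromosomes I, III and V were tested on II, IV and X. Another 5 sequences were fixed beforehand. The tests of annotation classes and of sequences by kind of peak were added after the data were seen.

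Before the data were examined, 31 gene lists were fixed as name patterns of C. elegans genes, and genes were counted where the annotation name matched. The lists cover ribosomal proteins, mitochondrial ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, proteasome, respiratory chain and ATP synthase, spliceosome, RNA polymerase II and general transcription, histones, chromatin regulators, DNA replication and repair, and cell cycle and mitosis. They further cover P granule and germline RNA regulators, small RNA pathway, sperm, intestine, muscle and neuron genes, neuropeptides and insulins, collagens and cuticle, chemoreceptors, F-box and BTB families, C-type lectins, cytochrome P450 and UGT, nuclear hormone receptors, homeobox genes, the MADF family, heat shock and chaperones, vesicle traffic, the ubiquitin system, and nuclear pore and transport. Each was tested against all other protein-coding genes. A name pattern can take in genes of another function, and several genes are on more than 1 list. Genes were named by a rule fixed at the same time: madf-10 and unc-119; the 25 genes nearest to the strongest promoter peaks that overlap the strongest 1869 regions of both replicates, with 1 gene per peak; and up to 3 members with the strongest promoter peak for each list past the threshold. Because 9 of the 25 were mitochondrial, the 25 strongest nuclear genes were also taken, which was decided after the data were seen.

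The scripts were tested on simulated lists of 1869 peaks over 19985 genes. With 50% of the peaks planted in promoter windows, the recovered promoter share was 61.1%, where 25.6% of random positions fell in such windows. A planted log2 signal difference of 1 in the planted peaks was recovered as 0.82, since other peaks also fell in windows. All 3 planted gene lists were called and 0 others. In 620 list tests with nothing planted, 2 calls were made. Those tests drew single genes at random and no peaks. They therefore do not cover the dependence between neighbouring genes that share a peak. A planted 6-base sequence ranked 1, and 10 sequences were called in that simulation, so a called sequence can be a neighbour of the planted one. Of 100 permutation tests without a difference, 4 had a p below the threshold. The alternatives were a stricter list, each replicate alone, other promoter windows, random positions or narrower backgrounds, other overlap rules, the other genome build, other expectations for chromosomes and other sequence windows. Without mitochondrial peaks, without peaks near tRNA genes and with as many regions as the ce10 list holds were added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.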

Results

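Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where MADF-10 was found on the Caenorhabditis elegans genome. MADF-10 belongs to the worm proteins with a MADF domain, a fold related to the Myb DNA-binding domain. Worms of strain OP508 carried MADF-10 with GFP and FLAG joined to its C terminus, and chromatin was pulled down with an antibody against GFP. Whole hermaphrodites were collected as young adults, 68 h after the release of synchronised L1 larvae. The design held 1 group of 2 biological replicates, so it allowed a comparison of the replicates with each other and of strong with weak regions, and no comparison between conditions. The authors' lists held 25924 regions for replicate 1, 30000 for replicate 2 and 30000 for both replicates pooled, on genome build ce11. Each region carried the authors' signal value, with a median of 10.8 in replicate 1, 17.9 in replicate 2 and 23.3 in the pooled list. The number of reads behind these lists is not given in the sources used here, so signal values were compared only within a list.

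The promoter of madf-10 itself held the third strongest region of the pooled list. This region lay on chromosome I from 10437510 to 10438412, with its summit at 10438019, 240 bp upstream of the annotated start of madf-10 (WBGene00013717, 10436895 to 10437779, minus strand). It covered the 5' part of madf-10 and the 3' end of the neighbouring gene pdpr-1. Its signal was 13878 in the pooled list, 4214 in replicate 1 and 9726 in replicate 2, and it ranked 3 in each list. That was 596 times the median of the pooled list, 389 times the median of replicate 1 and 544 times the median of replicate 2. The strongest other region within 15 kb, at 10435677 to 10436049 in the shared promoter of pab-1, which encodes poly(A)-binding protein, and rpl-30, had a signal of 508. The neuronal gene unc-119 is mutated in the strain background. The plan of the work took it as the marker of the strain's transgene, present in extra copies. Its strongest pooled region (chromosome III, 10905025 to 10905444) had a signal of 38.0 and rank 7040. No reproducible peak lay within 5 kb of unc-119. Per the labels, the strain carries an integrated transgene, and its number of copies is not given in the sources used here.

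**Figure D1:**
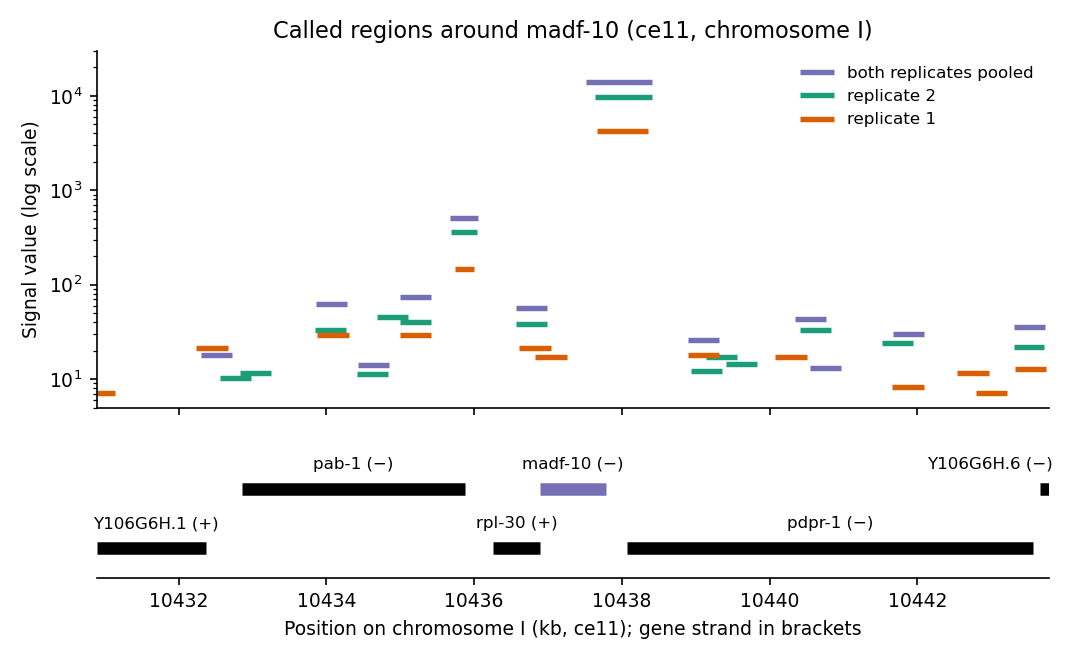
Regions called around madf-10 on chromosome I (ce11), drawn as horizontal lines at their signal value (log axis) for the pooled list and for each replicate, above the protein-coding genes with their strand. The region upstream of madf-10 had a signal of 13878 in the pooled list, 4214 in replicate 1 and 9726 in replicate 2, and the next strongest region drawn had 508, 147 and 366 in the same lists.

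The authors' list of reproducible peaks, which passed their irreproducible discovery rate (IDR) threshold, held 1869 peaks on ce11. These peaks formed 1805 separate stretches and covered 0.652 Mb, with a median width of 420 bp and signal values from 92.3 to 19717. The strongest peak lay on chromosome V from 20777792 to 20779270 and had no annotated gene within 1 kb of its summit. The peak of rank 2, on chromosome V from 6226212 to 6230018, had a signal of 17149.7 and its summit 750 bp upstream of a start of W06H8.6. Of the 1869 strongest regions of replicate 1, 1403 (75.1%, exact 95% interval 73.0 to 77.0) shared at least 1 bp with the 1869 strongest of replicate 2, against a mean of 2.70% and a highest value of 3.85% in 1000 random placements (p = 0.001, the smallest that these placements can give). Across the 1857 peaks with a region in both replicates, log2 signal had Pearson's r = 0.880 and Spearman's rho = 0.664 (2-sided permutation test, p = 1e-05 for each, the smallest it can give). Across the 1835 such peaks outside the mitochondrial DNA, a setting added after the data were seen, r was 0.838 and rho 0.652. These are correlations across regions of 1 pair of libraries, and regions are not independent replicates. The peaks are also the strongest regions of the list pooled from the same 2 replicates. The list of the same experiment on build ce10 held 2878 reproducible peaks, 1.54 times as many, although the pooled lists of both builds held 30000 regions with a median signal of 23.3.

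**Figure D2:**
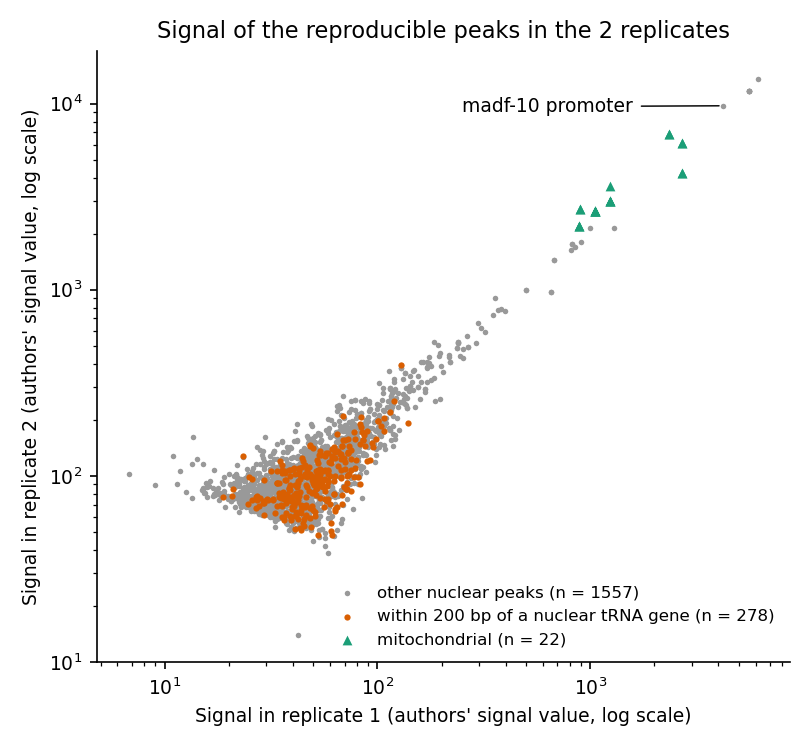
Signal value of each reproducible peak in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis) for the 1857 peaks with a region in both, with peaks near nuclear tRNA genes and mitochondrial peaks marked. Spearman's rho was 0.664, and the madf-10 promoter lay among the strongest peaks of both replicates.

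Apart from madf-10, the strongest promoter peaks of the nuclear genome lay at genes with a range of known functions. A peak on chromosome IV from 8758559 to 8759216 had a pooled signal of 3115 and lay inside the overlapping genes F20C5.11 and klp-11, which encodes a kinesin motor subunit. Its summit was 594 bp upstream of an internal transcript start of F20C5.11 and 639 bp upstream of one of klp-11. The peak upstream of gsa-1, which encodes the stimulatory G protein alpha subunit, had a signal of 2539. The peaks at K11D2.4 and T24B8.3, with signals of 2449.8 and 2105, had their summits inside the genes, 917 and 289 bp upstream of internal transcript starts. At din-1, which encodes a corepressor that acts with the nuclear receptor DAF-12, the summit also lay inside the gene, 8 bp upstream of an internal start, with a signal of 1164. Signals of 1147 and 1082 were found at vps-60, an ESCRT component, and at the kinesin gene klp-13. The peaks at tasp-1, a threonine aspartase, and rpl-3, a protein of the large ribosomal subunit, had signals of 962 and 929.9. Further peaks lay upstream of vha-13 (822), a subunit of the vacuolar proton pump, of epn-1 (758), which encodes epsin, of serp-1.1 (737) and of cdc-48.1 (699), the AAA ATPase also known as p97. The 25 strongest nuclear promoter peaks, a set chosen after the data were seen, went down to gmeb-1 with a signal of 521. All 25 ranked within the first 100 regions of both replicates. They were picked by their signal in the pooled list, which contains both replicates, so these ranks are not independent support. The rule fixed beforehand, without the restriction to nuclear genes, gave 16 nuclear and 9 mitochondrial genes.

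Summits of reproducible peaks lay near the transcript starts of protein-coding genes more often than those of weak regions did. In all, 1015 of the 1869 summits (54.3%, exact 95% interval 52.02 to 56.6) lay from 1000 bp upstream to 200 bp downstream of an annotated transcript start. Among the 14838 weak regions, those in the lower 50% of the pooled list by signal, the share was 28.6% (Fisher's exact test, 2-sided, p = 3.98e-105, odds ratio 2.97). In the replicates' own lists of strongest regions the share was 52.8% and 55.6%, a mean of 54.2% ± 2.01 (SD, n = 2), so the difference from the weak regions exceeded the spread between replicates. Of the summits in promoter windows, 93.3% lay upstream of the start, at a median of -233 bp. The window itself reaches 1000 bp upstream and only 200 bp downstream. This share was not compared with that of weak regions or random positions. Fewer peaks than weak regions lay in coding sequence (2.51% against 19.5%, adjusted exact p = 1.85e-102) and in introns (17.2% against 29.2%, adjusted exact p = 1.43e-29), by Fisher's exact test with Benjamini-Hochberg adjustment over 7 kinds of annotation. Non-coding genes and pseudogenes held 5.78% of the summits and 1.78% of the weak regions (adjusted exact p = 2.85e-21). The median distance to the nearest protein-coding transcript start was 608 bp for peaks and 1170 bp for weak regions (permutation test, p = 1e-05). Peaks in promoter windows were not detectably stronger than other peaks, with median signals of 139.9 and 135.7 and a log2 difference of 0.04 (permutation test, p = 0.236). Annotated starts of worm genes are often trans-splice sites that lie downstream of the site where transcription begins, so a distance is to the annotated start only.

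**Figure D3:**
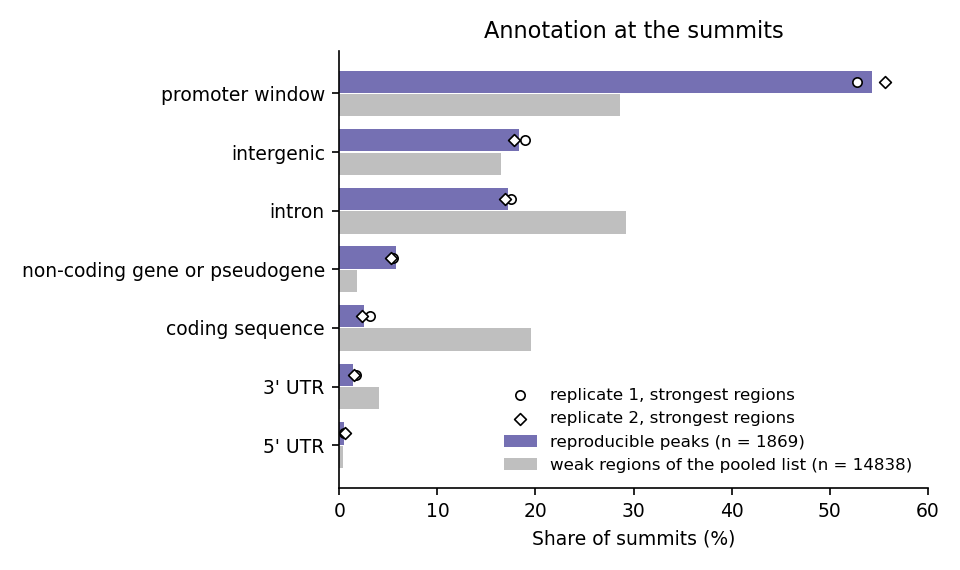
Share of summits in each kind of annotation for the reproducible peaks and for the weak regions of the pooled list (bars), with the share among the strongest regions of each replicate (points). Promoter windows held 54.3% of the peaks and 28.6% of the weak regions, and coding sequence held 2.51% and 19.5%.

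The promoter windows of 1275 of the 19985 protein-coding genes (6.38%) held a reproducible peak, and 1209 and 1280 genes did so in the replicates' own lists (mean 1244.5 ± 50.2, SD, n = 2). A gene is called bound below where a summit lay in its promoter window, whether at its outermost or an internal transcript start. Of the 1015 peaks in promoter windows, 307 (30.2%) counted for 2 or more genes. With each peak counted for its nearest start only, 967 genes were bound. The peaks were not compared with regions where many factors are found in worm ChIP-seq, so a bound gene is not shown to be specific to MADF-10. Genes for cytosolic ribosomal proteins were the list bound most often. Of 82 genes for cytosolic ribosomal proteins, 47 (57.3%) had a promoter peak, against 6.17% of the other protein-coding genes (log2 odds ratio 4.35, Fisher's exact test with Benjamini-Hochberg adjustment over 31 lists, adjusted exact p = 1.87e-33). The share was 48.2% ± 0.862 (SD, n = 2) in the replicates' own lists. The strongest of these peaks were at rpl-3 (929.9), rpl-15 (649.9) and rpl-20 (612). The summit at rpl-20 lay 285 bp from its start and 177 bp from that of the neighbouring gene Y17G9B.5. Of 41 translation factor genes 11 (26.8%) were bound (adjusted exact p = 0.000125), among them iff-2, which encodes the initiation factor eIF5A, with a signal of 427. Of 47 genes of the respiratory chain and ATP synthase 16 were bound (adjusted exact p = 8.08e-08), led by the cytochrome oxidase genes cox-5A (463), cox-5B (338) and cox-6B (256).

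Genes for chromatin, protein folding and membrane traffic also had promoter peaks more often than other genes. Among 143 genes for chromatin regulators 34 (23.8%) were bound (adjusted exact p = 1.20e-10), with signals of 414 at lin-54, the DNA-binding subunit of the DREAM complex, 389 at the histone acetyltransferase gene cbp-1 and 385 at the histone methyltransferase gene set-16. Heat shock and chaperone genes were bound in 24 of 97 cases (24.7%, adjusted exact p = 3.95e-08), including hsp-3 (343), hsp-90 (337) and hsp-60 (319). Vesicle traffic genes were bound in 40 of 162 cases (24.7%, adjusted exact p = 6.86e-13), with vps-60 the strongest. Lists with smaller excesses were those of the ubiquitin system (19 of 96, adjusted exact p = 3.35e-05), cell cycle and mitosis (19 of 96, adjusted exact p = 3.35e-05), nuclear pore and transport (10 of 51, adjusted exact p = 0.00258) and DNA replication and repair (12 of 65, adjusted exact p = 0.00179). The spliceosome list had 15 of 86 genes bound (adjusted exact p = 0.00101), RNA polymerase II and general transcription 12 of 80 (adjusted exact p = 0.00842) and the small RNA pathway 8 of 56 (adjusted exact p = 0.0429). The small RNA pathway no longer passed with replicate 1 alone (adjusted exact p = 0.204) or with the stronger 50% of the peaks (0.189). Nor did it with the wide promoter window (0.0824) or with the nearest start only (0.252). Its log2 odds ratio was 1.37 in the main setting, 1.00 with replicate 1 alone, 1.32 with the stronger 50% and 1.10 with the wide window. RNA polymerase II and general transcription no longer passed with the narrow or the wide promoter window (adjusted exact p = 0.0969 and 0.0733). With the nearest start only, heat shock and chaperones and nuclear pore and transport did not pass either (adjusted exact p = 0.0521 and 0.0651). Named members were eel-1, ubc-9 and wwp-1 of the ubiquitin system, and npp-3, nxt-1 and npp-6 of nuclear pore and transport. The spliceosome list had mog-4, prp-19 and rsp-6. The cell cycle list was led by klp-11 (3115) and klp-13 (1082), ahead of smc-3 of the cohesin complex (233). DNA replication and repair was led by lig-4 (303), ahead of top-2 and pcn-1. RNA polymerase II and general transcription had mdt-8 of Mediator, rpac-19 and mdt-26. The small RNA pathway was led by ekl-4 (299), ahead of nrde-2 and ego-1 of RNA interference. The same peak (chromosome II, 11874768 to 11874993) counts for both npp-3 and top-2.

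Chemoreceptors and several other large gene families were bound less often than other genes. Of 1310 chemoreceptor genes 10 (0.763%) had a promoter peak, against 6.77% of the other genes (adjusted exact p = 1.02e-24). The shares were 1 of 144 for neuropeptides and insulins (adjusted exact p = 0.00315), 7 of 324 for collagens and cuticle genes, 11 of 417 for the F-box and BTB families and 4 of 240 for C-type lectins (adjusted exact p = 0.00179 for each of the last 3 lists). With the stronger 50% of the peaks, neuropeptides and insulins, collagens and cuticle genes and the F-box and BTB families no longer passed (adjusted exact p = 0.167, 0.152 and 0.104). Among the few bound members were srbc-82 (687), ins-39 (394), fbxb-58 (475), nas-10 (225) and clec-126 (250). The other 13 lists did not pass the threshold. They held histones (2 of 82), mitochondrial ribosomal proteins (9 of 66), the proteasome (4 of 33), aminoacyl-tRNA synthetases (2 of 31), the MADF domain family (2 of 10, of which 1 is madf-10 itself) and cytochrome P450 and UGT genes (4 of 141). They also held nuclear hormone receptors (14 of 274), homeobox genes (2 of 95) and the tissue lists of P granule and germline regulators (9 of 88), sperm (2 of 92), intestine (8 of 102), muscle (2 of 54) and neurons (3 of 129). When the background was narrowed to the 4850 genes with any weak region or peak in the promoter window, 7 lists stayed past the threshold on the high side and 0 on the low side. The 7 were ribosomal proteins, respiratory chain, chromatin regulators, heat shock and chaperones, vesicle traffic, the ubiquitin system, and nuclear pore and transport. This background leaves out genes whose only promoter regions ranked between the peaks and the lower 50% of the pooled list. The F-box and BTB families had a log2 odds ratio of -1.29 against all genes and -0.01 in this background, C-type lectins -1.85 and -0.20, chemoreceptors -3.17 and -1.08, collagens and cuticle genes -1.55 and -1.06, and neuropeptides and insulins -2.72 and -2.22. Translation factors had 2.48 and 1.26. In this background they no longer passed on the high side. Nor did cell cycle and mitosis, DNA replication and repair, the spliceosome, RNA polymerase II and general transcription, or the small RNA pathway. With each replicate alone, 13 to 14 lists were bound more often and 6 to 7 less often, but not all were the lists above. Replicate 1 alone added the MADF domain family on the high side (3 of 10 genes with madf-10 itself among them, log2 odds ratio 2.86, adjusted exact p = 0.0314) and neuron genes and cytochrome P450 and UGT genes on the low side (adjusted exact p = 0.0387 and 0.0220). Replicate 2 alone added the proteasome on the high side and sperm genes on the low side (adjusted exact p = 0.0278 and 0.0475). Neighbouring genes can share a peak, so these p-values describe the lists and not independent genes. With each peak counted for its nearest start only, 10 lists were bound more often and 5 less often.

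**Figure D4:**
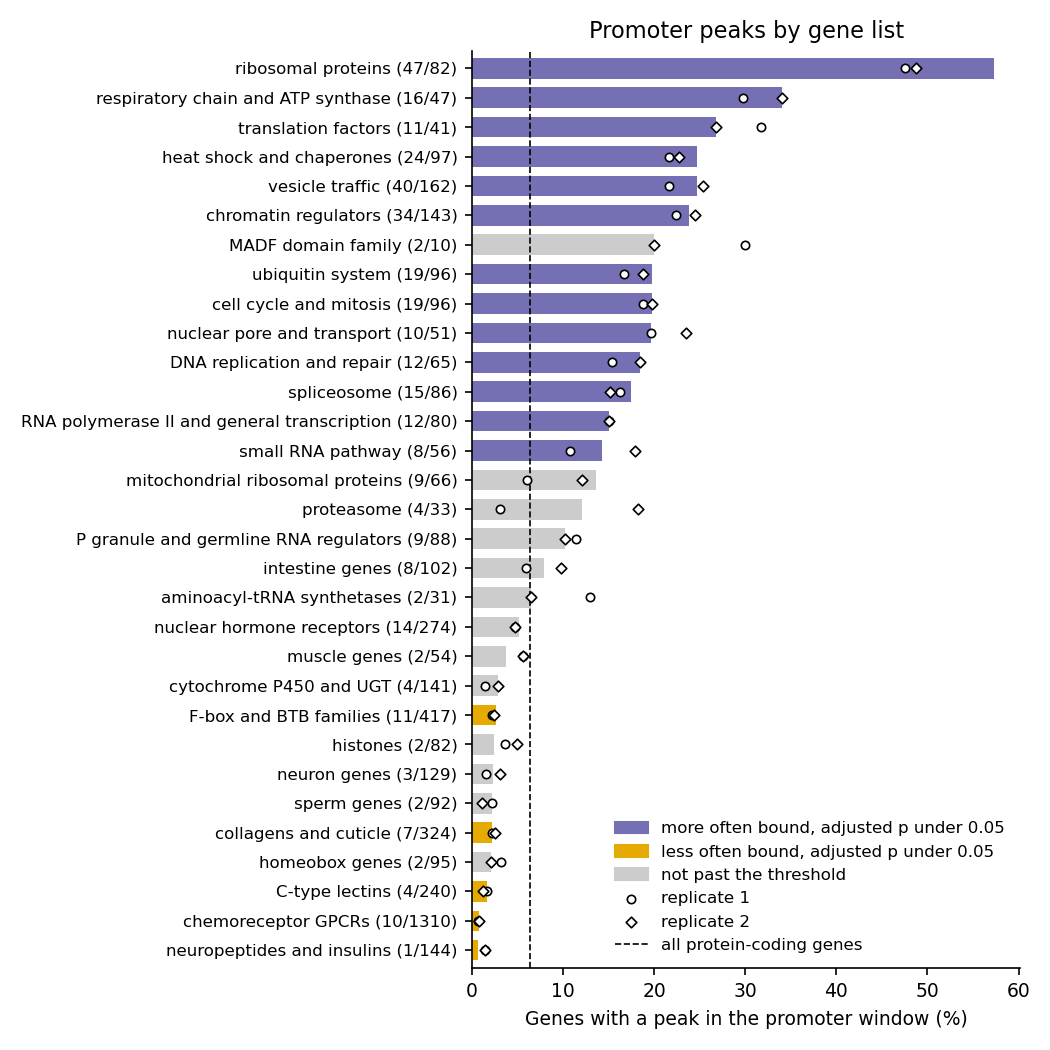
Share of the genes of each of 31 lists with a reproducible peak in the promoter window (bars, with bound and total genes in brackets), the same share in each replicate's strongest regions (points) and the share over all protein-coding genes, 6.38% (dashed line). Ribosomal protein genes had the highest share, 57.3%, and 13 lists lay above and 5 below the other genes past the adjusted threshold.

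Transfer RNA genes were the most frequent at peaks among the 5 classes of non-coding genes tested. Of the 1869 summits, 290 (15.5%, exact 95% interval 13.9 to 17.2) lay within 200 bp of a tRNA gene, against 0.216% of the weak regions (Fisher's exact test, adjusted over 5 classes, p = 2.37e-242) and 0.66% of random positions (adjusted exact p = 4.02e-196), and the share was 15.4% ± 1.63 (SD, n = 2) in the replicates' own lists. Of the 634 annotated tRNA genes, 317 had a peak. Peaks near tRNA genes were not detectably stronger than other peaks, with median signals of 142 and 137 (permutation test, p = 0.331). Small nucleolar RNA genes lay near 78 summits (4.17% against 0.364%, adjusted exact p = 3.63e-40), and only 1 of these summits was in the promoter window of a ribosomal protein gene. Small nuclear RNA genes lay near 21 summits (1.12% against 0.0876%, adjusted exact p = 3.46e-12) and microRNA genes near 9 (0.482% against 0.128%, adjusted exact p = 0.00256). Ribosomal RNA genes lay near 5 summits, all of them mitochondrial. The mitochondrial DNA held 0 weak regions, so the weak regions are no background for this class, and against random positions it did not pass the threshold (0.268% against 0.18%, adjusted exact p = 0.394). Of the summits near tRNA genes 7 were mitochondrial.

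Chromosome X carried more peaks than its number of genes would give. Of the 1847 nuclear peaks 412 (22.3%, exact 95% interval 20.4 to 24.3) lay on X, which holds 13.7% of the nuclear protein-coding genes (exact binomial test, 2-sided, p = 1.02e-23) and 17.7% of the nuclear sequence (p = 3.95e-07). This amounted to 23.3 peaks per Mb on X and 17.4 on the autosomes, and the X share was 22.2% ± 0.0979 (SD, n = 2) in the replicates' own lists. Chromosome III, the densest autosome, carried 22.9 peaks per Mb and chromosome V 13.2. X also held 276 of the 634 tRNA genes, and 139 of its peaks lay near one. Without the peaks near tRNA genes, an alternative chosen after the data were seen, the X share was 17.5% (15.6 to 19.4). The middle 33.3% of the nuclear chromosomes held 39.4% of the peaks and 37.8% of the protein-coding genes, a difference that did not pass the threshold (exact binomial test, p = 0.164). It did pass against the share of sequence length (p = 6.22e-08, exact binomial test), and against the share of genes with as many regions as the ce10 list holds (p = 0.000264) and without peaks near tRNA genes (p = 0.0325), the last 2 chosen after the data were seen.

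**Figure D5:**
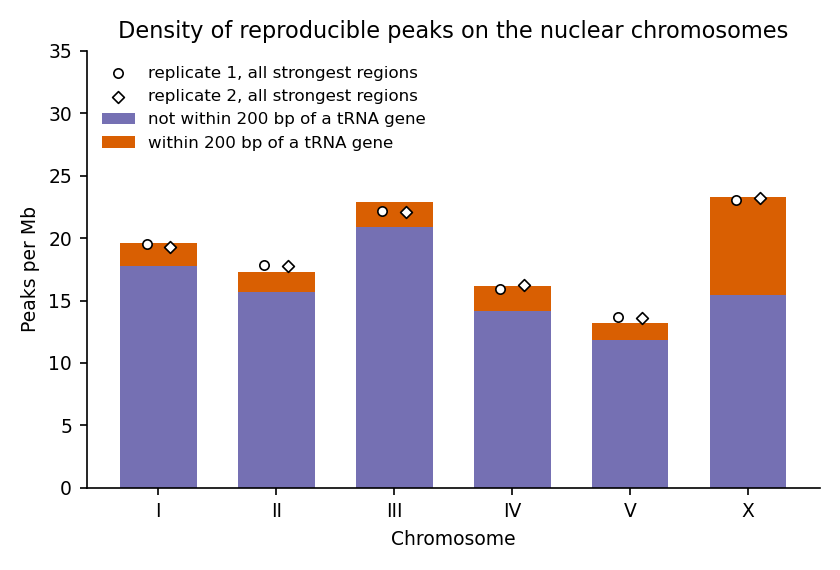
Reproducible peaks per Mb on each nuclear chromosome, divided into peaks within and beyond 200 bp of a tRNA gene (stacked bars), with the density of the strongest regions of each replicate (points). X had 23.3 peaks per Mb, of which 139 of 412 peaks lay near a tRNA gene.

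The sequence at promoter peaks was richer in G and C than at weak regions that also lay in promoter windows. The mean GC content from 100 bp upstream to 100 bp downstream of the summit was 44.2% ± 7.33 (SD, n = 1015 peaks) against 36.3% ± 7.73 (SD, n = 4239 weak regions), a difference of 7.94 percentage points (permutation test, p = 1e-05). The difference was 7.41 and 7.95 points in the replicates' own lists. Of the short sequences, GAGAGA had the largest excess in the discovery chromosomes I, III and V, and on the held-out chromosomes II, IV and X it was present in 22.4% of the windows that reach 50 bp to either side of a summit and 6.10% of the flanking windows (Fisher's exact test, adjusted over 10 sequences, p = 5.08e-35). ACGCAG was present in 13.5% of the summit windows and 2.03% of the flanks (adjusted exact p = 3.25e-32), and AGACGC in 13.3% and 1.98%. All 10 sequences picked on the discovery chromosomes passed the threshold on the held-out chromosomes, and several of them share bases with each other. Over all chromosomes CTGCGTCT, which contains the reverse complements of ACGCAG and AGACGC, was present in more windows at summits than in the flanks (7.76% against 0.482%, adjusted exact p = 1.02e-50). CCGCCC was present in 6.47% and 1.77% of the windows (adjusted exact p = 7.84e-19). GGTTCGANNCC, the B box of the internal promoter of tRNA genes, was present in 4.92% and 0.375% (adjusted exact p = 1.69e-30). Of the 92 summit windows with this sequence, 82 were at peaks near tRNA genes. Runs of T were scarcer at summits, with TTTTTT in 20.5% of the windows and 41.5% of the flanks (adjusted exact p = 7.75e-57). Summit and flanking windows were not matched for base composition, so none of these differences is corrected for it.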

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

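The tests of the X share against sequence length with and without peaks near tRNA genes, of added copies as the whole of the madf-10 signal, and of shared reads as the whole of the tRNA peaks were chosen only after the results were seen. No biological explanation was tested for any pattern below, since the design has 1 group.

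The mitochondrial DNA held 22 reproducible peaks, which were part of the promoter, gene and non-coding comparisons but not of the chromosome comparisons. These peaks covered 10826 of its 13794 bp (78.5%), with a median signal of 2855 against 137 for nuclear peaks, and 19 of the 30 strongest peaks were mitochondrial.

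The region at the promoter of madf-10 ranked 3 in both replicates, in a strain that carries a tagged transgene of madf-10. Reads that match other places are argued against, since 100% of its 36-base stretches occur once in the reference. Added copies of madf-10 and its flanks may contribute. The summed signal of the other regions within 15 kb was 1236, at the 99.5 percentile of 1000 random genes, whose 95th percentile was 760. A peak of 508 at pab-1 and rpl-30 makes up much of this sum. Without it the sum would lie below that 95th percentile, although the random genes lost only their strongest region. The peak at pab-1 and rpl-30, the strongest other region, reached 3.66% of the signal of the promoter region. The 21 other regions, of which 2 were reproducible peaks, had a median 1.25 times that of the pooled list. These values argue against added copies as the whole of the signal only for copies that span these flanks. At unc-119, taken as the marker of the transgene, the strongest pooled region had 1.63 times the median of the pooled list. The extent of the transgene is not known here, nor which part of unc-119 it holds, so the unc-119 value does not decide this. Copies of the promoter alone, binding to it by MADF-10 and an effect of the tagged, transcribed transgene on the pull-down all stay open.

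Peaks at tRNA genes could come from reads that match several identical copies, and the tests left this open. Of 140 nuclear tRNA genes with a sequence found once, 46 (32.9%) had a peak, against 261 of 472 (55.3%) with identical copies, a ratio of 0.594 (Fisher's exact test, p = 3.35e-06). Of 63 genes with 50% or more, but not all, of their 36-base stretches occurring once, 30 (47.6%, exact 95% interval 34.9 to 60.6) had a peak, against 14 of 51 (27.5%, 15.9 to 41.7) with fewer such stretches and 55.4% of fully shared genes, and the differences between these sets were not tested. None of the 21 isolated genes without a shared stretch had one (0 of 21, upper bound 16.1%), an interval that holds the 0.825% at random positions, and this set, which alone made up the test in its earlier form, would by itself have counted for shared reads. Such isolated genes can differ from the rest in being transcribed at all, which was not tested, so shared reads and binding at transcribed tRNA genes cannot be told apart.

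The excess of peaks on X was larger than the tRNA genes or the lower gene density of X would each give. Without peaks near tRNA genes the X share was 17.5% (15.6 to 19.4), still above the 13.7% of genes, and with all peaks it was 22.3%, above the 17.7% of sequence length. Both at once, the tRNA genes and the length of X could account for the excess, since 17.5% without those peaks lay within counting error of the 17.7% of sequence length (exact binomial test, p = 0.842). This combination was noticed in the same data and is a hypothesis.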

How the results depend on the processing

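The following settings were added after the data were seen: without mitochondrial peaks, without peaks near tRNA genes, and with as many ce11 regions as the ce10 list holds. Across settings, 97 values for the main results kept their direction and side of the threshold, or stayed within 1.5 times for counts, 6 counts moved further and 3 values passed the threshold anew; for single lists, classes and sequences the numbers were 349 unchanged, 12 past the threshold anew, 23 no longer past it and 1 reversed. With the stronger 50% of the peaks, there were 934 peaks at 666 genes, as that setting has fewer peaks, and 2 lists less often bound, where the cause was not tested. The ce10 list held 2878 peaks, and the cause was not tested. With genes that have a weak region or reproducible peak in the promoter window as background, 7 lists were more and 0 less often bound. The odds ratios of lists no longer past the threshold were also nearer to 1, and the cause was not tested. The share of peaks in chromosome centres passed the threshold against sequence length (39.4%, exact binomial test, p = 6.22e-08), with as many regions as the ce10 list holds (41.1%, p = 0.000264) and without peaks near tRNA genes (40.4%, p = 0.0325); the cause was not tested. Without mitochondrial peaks, 0 peaks lay near ribosomal RNA genes, since all 5 of that class were mitochondrial. As 0 weak regions lay near such genes too, this comparison has no direction. It is the 1 value counted as reversed above. Mitochondrial ribosomal proteins passed the threshold with the wide promoter window, with as many regions as the ce10 list holds and without peaks near tRNA genes (adjusted exact p = 0.00627, 0.0485 and 0.0290). Further lists past the threshold anew were P granule and germline regulators on the high side with the stronger 50% of the peaks (0.00816), cytochrome P450 and UGT genes on the low side with the narrow promoter window (0.00309), and intestine genes and the proteasome on the high side with as many regions as the ce10 list holds (0.0161 and 0.0485). The promoter share ranged from 52.8% to 55.6% with each replicate alone. With the narrow window, 500 bp upstream to 100 bp downstream, it was 43.2% against 16.7% of weak regions. With the wide window, 2000 bp upstream to 500 bp downstream, it was 67.4% against 48.7%. Without peaks near tRNA genes it was 59.6% against 28.6%. No paired analysis was possible because there is 1 group. The X share on ce10 was not run, as chromosome lengths of that build were not used here. Read depth is unknown, so the number of peaks that more reads would give cannot be stated.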

Other observations

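The values in this part were looked at only after the data were seen. Of the 30 strongest nuclear peaks, 12 lay in introns or between genes. Intronic peaks with signals of 1492, 752 and 749 lay in lin-14, a timing gene of larval development (chromosome X, 11472950 to 11473682), in let-526, which encodes a subunit of a chromatin remodelling complex (chromosome I, 5312751 to 5313468), and in daf-12, the nuclear receptor (chromosome X, 10637250 to 10637818). The gene of its corepressor, din-1, held 2 peaks in its promoter windows, with signals of 1164 and 375. Peaks between genes with signals of 2687 and 1166 lay on chromosome X from 16024486 to 16025119 and on chromosome III from 4281906 to 4282640, with no annotated gene within 1 kb of the summit. Of the 36-base stretches of the strongest peak of all, on chromosome V, 99.8% occurred once in the reference, and the lowest such share among the 10 strongest nuclear peaks was 98.46%.

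The sequences at summits were counted by kind of peak, and peaks near tRNA genes were not tested against the others. CTGCGTCT was present at 1 of 290 peaks near tRNA genes (0.345%), at 88 of 941 other promoter peaks (9.35%) and at 56 of 638 peaks that were neither (8.78%). The last 2 shares did not differ detectably (Fisher's exact test, adjusted over 8 tests, p = 0.904). GAGAGA was present in 11.4%, 23.9% and 26.6% of the same sets. At promoters of ribosomal protein genes CTGCGTCT was present in 3 of 44 peaks and GAGAGA in 7 of 44, against 9.48% and 24.3% of other promoter peaks, and neither difference passed the threshold (Fisher's exact test, adjusted p = 0.904 and 0.553). The B box sequence GGTTCGANNCC was present at 82 of 290 peaks near tRNA genes (28.3%), which follows from how these peaks were chosen, since it lies within tRNA genes. It was present at 1 of the 941 other promoter peaks (0.106%) and in 1.41% of the peaks that were neither, the 1 difference of the 8 tests that passed the threshold (Fisher's exact test, adjusted p = 0.0142). Of the nuclear tRNA genes, 151 of 276 on X (54.7%) and 156 of 336 on autosomes (46.4%) had a peak (Fisher's exact test, p = 0.0427, odds ratio 1.39). Of the 1310 chemoreceptor genes, 71 had any weak region or peak in the promoter window.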
